A study of Schizosaccharomyces pombe with 13 samples.

How the data were processed

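The series measured incorporation of newly made histone H3 in the fission yeast Schizosaccharomyces pombe with 13 two-colour Agilent arrays, 1 array per genotype. Per the labels' protocols, FLAG-tagged H3 was placed under the sucrose-responsive inv1 promoter, cells were arrested with hydroxyurea before induction, chromatin was crosslinked with formaldehyde and cut to mononucleosomes with micrococcal nuclease, and FLAG-bound DNA was compared with the whole cell extract. Cy5 carried the FLAG immunoprecipitate and Cy3 the whole cell extract on all arrays, per the labels, with no dye swap.

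The deposited intensity values were the red and green processed signals of Agilent Feature Extraction, version 10.10.1.1 for 9 arrays and version 11.0.1.1 for clr3Δ, epe1 overexpression and both K-deletion strains, per the file headers. Per the file headers these intensity values were background-subtracted, corrected by multiplicative detrending and scaled with a linear dye factor, with no lowess step (a lowess root mean square of 0). A genome build was named only in the headers of the second array design, an older NCBI build, and it is not given in the sources used here for the first. Positions below are those printed for the probes in the files. Their 4th sequence, which holds the mating-type locus, is called the mating-type contig.

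The first design (11 arrays) held 43993 probes in 11 tiled blocks of 440 kb in all, and the second (2 arrays, both K-deletion strains) 39589 probes in 9 blocks of 396 kb, with 60-bp probes in both. H3-FLAG ratios were compared only between arrays of 1 design, while extract signals over the mating-type region were also compared between designs at shared probes. The measure was log2 of Cy5 over Cy3, minus the median of all probes of the array, so each value is relative to the tiled probes and not to the whole genome. Control spots, spots marked as non-uniform or population outliers and probes whose whole cell extract signal was not well above background on both arrays compared were left out. Saturated spots were kept. The whole cell extract was well above background for 97.0% to 99.97% of probes. Outlier marks removed 37.62% of spots on the chp2Δ array, 33.25% on the epe1Δ array and 14.09% on the dcr1Δ array, and at most 0.5% on the others. Saturation affected 16.9% of spots on the clr3Δ array and none elsewhere. For arrays the number per genotype limits the precision, and here that number was 1.

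Because the reference genome in use (ASM294v3) was another build, coordinates were not carried between builds. Instead, windows of the arrays were placed on the reference by correlating whole cell extract brightness along the window with a model of brightness from base composition. On chromosomes I to III the match was sought within 3 kb of the printed position on the same chromosome. This placed 21 of 28 windows with 94.4% of probes, at correlations of 0.291 to 0.483. A search of the whole reference gave the same place for these windows, except that the ura4 block matched chromosome I better (0.484 against 0.453), so its place rests on the printed position. Gene names were then read from the reference annotation at the placed windows, which covered 210 genes without long noncoding RNAs, 156 of them protein-coding. A pair of blocks on chromosome III and the part of the mating-type contig outside its first 20 kb could not be placed, so no genes are named there. Probes were called unique when no second copy in the reference matched at 50 or more bases in BLAST+ 2.17.0. In the centromere 2 arms these lay at the outer ends, 1604171 to 1604640 on the left and 1644791 to 1645640 on the right.

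Region limits were set on array positions after the files were read. The centromere 2 arms were chromosome II 1603318 to 1619482 and 1629483 to 1645648, around a 10-kb centre. The silent mating-type region was positions 19231 to 39820 of the mating-type contig, bounded by inverted repeats found from the mirrored whole cell extract profile (best correlation 0.58). A stretch at 28661 to 33000, next to the part lost from the K-deletion strains, is taken to resemble the centromere repeats and is called the cenH-like stretch. It could not be placed on the reference, so the resemblance was not checked by sequence. It starts where the loss from the K-deletion extracts ends, and its end at 33000 was a fixed limit. The subtelomere was the first 50 kb of chromosome I, the single chromosome I or II end tiled. Of its 4889 probes 369 (7.5%) were unique, so its values and those of its genes can read similar sequence from elsewhere. On chromosome III, the first 23130 bases carried rDNA-like sequence and were kept apart from 23131 to 50000. Short tiled edges of centromere 1 (chromosome I 3751600 to 3756599) and centromere 3 (chromosome III 1069105 to 1074104) were reported separately. Of their probes 37.6% and 15.2% were unique, so they can read repeat DNA from elsewhere, and no processing alternatives were run for them. Euchromatin was the rest of chromosomes I to III and the mating-type contig left of the inverted repeats. The 5 kb on either side of centromere 2 were left out of it, and no such flank was left out beside the other regions.

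A region's level was the median over its probes and a comparison was the median of per-probe differences, each with its interquartile range. With 1 array per genotype there was no test across samples. Each median was placed among 10000 random lists of euchromatic probes matched on brightness in 20 bins and among 10000 runs of neighbouring euchromatic probes of the same number. Those runs overlap, because they were drawn from 25805 euchromatic probes in the first design while the arms hold 3116 probes and the subtelomere 4889. An extreme percentile among runs thus rests on few separate stretches. Both kinds of percentile describe the arrays compared. Gene values were means over at least 3 probes, with genes lost from either whole cell extract by 3 or more on the log2 scale left out. Gene lists were described by the median over members and by the number of members at least 1 higher or lower on the log2 scale. A percentile was also taken among 10000 random gene lists, matched on mean log2 ratio and not on extract brightness. Named genes were, in each comparison, the 8 largest increases and 5 largest decreases of at least 1, at most 6 list members of that size per list, and at most 4 genes per region with the largest differences.

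The groups, the comparisons, the kinds of region, the gene lists, the rule for named genes and 11 kinds of alternative were chosen before the data were examined. The alternatives were normexp with an offset of 50 (on median signals, because mean signals were not used here), background-subtracted signals without dye scaling, loess within the array, scaling to a common spread, quantile normalization, centring on euchromatic probes, both channels above background, no filter on dim probes, means in place of medians for regions (medians in place of means for genes), unique probes and a 30-kb subtelomere. Random runs were an alternative to random lists. Keeping outlier-marked spots, dropping saturated spots, bounding the centromere by the inner tRNA genes and dropping the cenH-like stretch were added after seeing the data. The 15 gene lists covered meiotic genes silenced in islands or by RNA elimination, subtelomeric helicases, Tf2 retrotransposons, wtf genes, sucrose-responsive genes, glycolysis, ribosomal proteins, stress response, histones, cell-cycle genes of the MBF factor, mating and pheromone genes, heterochromatin factors, the manipulated loci and common marker loci.

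Region medians were tested on simulated data with 40 simulations per shift, and the mean recovered shift deviated by at most 0.07, with an SD between simulations of 0.02 to 0.15. A constant was added to the region's probes before their median was taken. This checks the calculation only, and not effects of repeats, brightness or single arrays. The gene step was tested on simulated data for clr4Δ against wild type. With 20 of 116 genes changed by 2 on the log2 scale in 20 simulations, 99.5% of the changed genes and 1.0% of the others passed the size limit of 1. The implanted change lay well past that limit, so the first share says little about genes near it. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.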

Results

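The data collected were 13 array profiles of FLAG-tagged histone H3 incorporated into chromatin of hydroxyurea-arrested fission yeast, each as the ratio of immunoprecipitate to whole cell extract. In such arrested cells, new H3 enters chromatin largely without replication, so a high ratio marks sites of frequent histone exchange. The strains were wild type, deletions (Δ) of clr4, dcr1, ago1, swi6, chp2, clr3 and epe1, the double deletions swi6Δ chp2Δ and ago1Δ epe1Δ, an epe1 overexpression strain, and a pair of strains in which the K region of the mating-type locus is replaced by ura4, in the OFF or the ON state. There was 1 array per genotype, so no difference below has a replicate check and no p-values are given. The arrays lay on 9 slides scanned on 9 days. Wild type, ago1Δ and ago1Δ epe1Δ shared a slide, as did clr4Δ with swi6Δ chp2Δ and OFF with ON, and every other array had a slide of its own. In any comparison between slides, those of clr4Δ and swi6Δ chp2Δ with wild type included, slide and genotype cannot be told apart. All 10 comparisons with wild type rest on the same wild-type array, and an error in it would enter each of them. Median signals were 13246 to 38812 for the extract and 8589 to 72074 for the immunoprecipitate, above local backgrounds of at most 102 in either channel. Over euchromatic probes, the arrays of the first design correlated pairwise at 0.39 to 0.81, with a median of 0.6. None of the deleted genes and no part of inv1 was tiled, so the genotype labels were not checked against the extract signal. The exception is that both K-deletion strains lost a stretch of the mating-type contig from the extract.

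In wild type, H3-FLAG was low over the centromere 2 arms, the left subtelomere of chromosome I and the silent mating-type region. The centromere 2 arms, which carry the outer repeats packaged in H3 lysine 9 methylated chromatin, had a median log2 ratio of -0.36 (interquartile range -0.54 to -0.13, 3111 probes), and 15.1% of probes lay above the array median, or a median of -0.14 over unique probes. The value over unique probes pools unlike outer ends. There, 500-bp bins of all probes stood at -0.95 and -0.52 on the left (1604001 to 1605000) and -0.51 and 0.09 on the right (1644501 to 1645500). The left subtelomere of chromosome I stood at -0.29 (-0.55 to -0.02), or -0.46 over unique probes, which are 7.5% of its probes. The silent mating-type region, which holds the unexpressed mating-type cassettes, stood at -0.27 (-0.58 to 0.07). The centre of centromere 2, where the kinetochore forms on CENP-A chromatin, stood at 0.11 (-0.59 to 0.67), or -0.35 after loess, the left end of chromosome III at 0.50 and its rDNA-like end at 0.93. Among 10000 random runs of neighbouring euchromatic probes, the arms and the subtelomere lay at percentile 0.0 and the mating-type region at percentile 1.6. The runs overlap and hold few separate stretches of such length. The tiled edges of centromeres 1 and 3 both stood at -0.11, at percentiles 34.2 and 32.8.

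**Figure D1:**
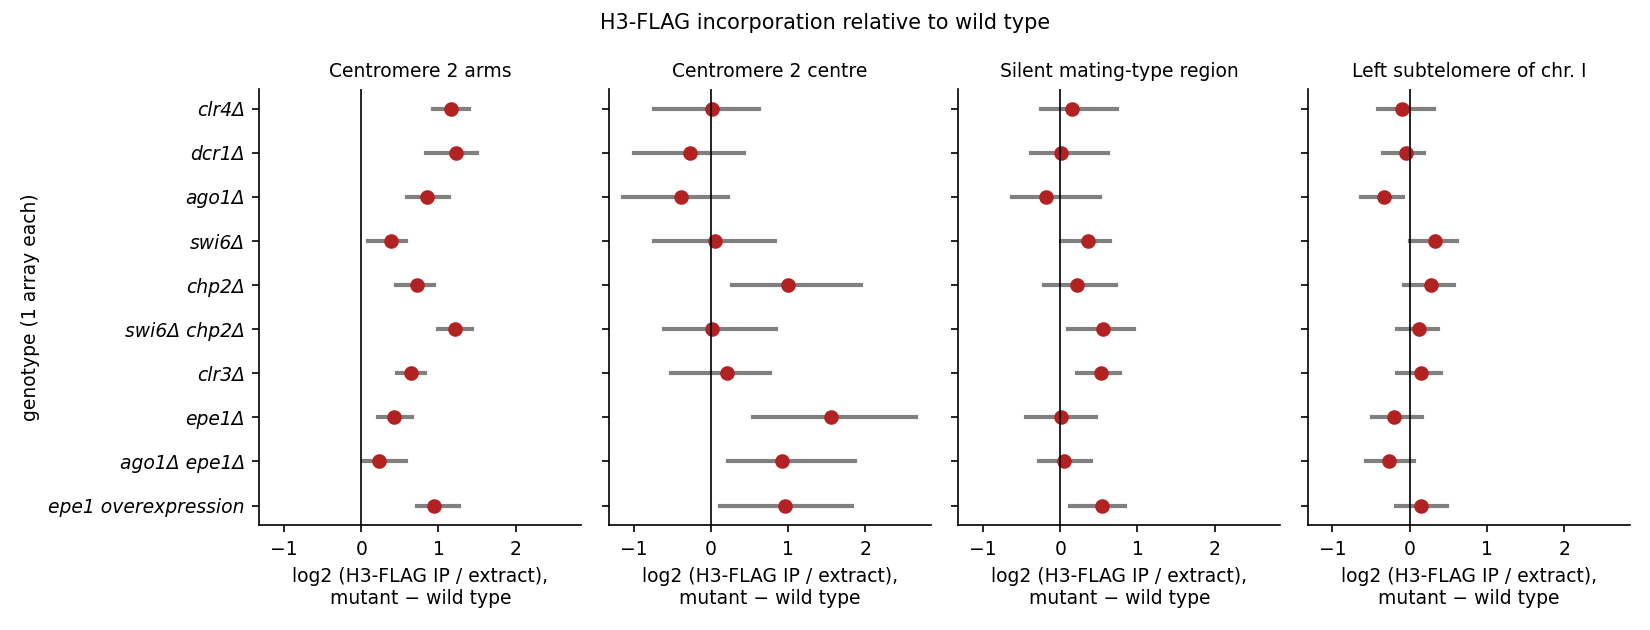
Median difference in log2 H3-FLAG ratio from wild type in 4 regions, with 1 point per genotype (1 array each) and bars spanning the interquartile range over probes. The centromere 2 arms lie above 0 in all 10 genotypes, from 0.23 in ago1Δ epe1Δ to 1.23 in dcr1Δ, before any restriction to unique probes.

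The comparison with clr4Δ asks how far exchange depends on Clr4, the sole H3 lysine 9 methyltransferase of fission yeast. Without clr4, H3-FLAG over the centromere 2 arms was 2.24-fold that of wild type, a median log2 difference of 1.16 (0.93 to 1.40, 3072 probes), and 94.6% of probes lay above 0. The tiled edges of centromeres 1 and 3 stood 0.55 and 0.80 above wild type, and the cenH-like stretch of the mating-type region 1.11 above it. The whole mating-type region stood at 0.15 (0.34 after loess, 0.27 with centring on euchromatic probes) but at -0.02 outside that stretch, the centre of centromere 2 at 0.01 and the 50-kb subtelomere at -0.10, although its terminal 30 kb stood at 0.19. There, tlh1, a subtelomeric RecQ-type helicase gene, was at 0.44 (SD over probes 0.25) and the neighbouring pseudogene SPAC212.09C at 0.55, while ftm2 stood at -0.52. The noncoding RNA gene SPNCRNA.363 in the arms stood at 0.89, and of 162 genes 1 was higher by 1 or more, the noncoding SPNCRNA.352 (1.1), and 0 were lower. The arms exceeded all 10000 random runs, whose highest value was 0.02. Of the arm probes 3.9% were unique, and over those the arm difference was 0.22, with 1.68 at the outer end of the left arm and 0.06 at that of the right arm. Loess within the array moved the centromere 2 centre to 0.49, and centring on euchromatic probes put the 50-kb subtelomere at 0.03.

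The dcr1Δ and ago1Δ arrays address the RNA interference pathway, in which Dicer (Dcr1) and Argonaute (Ago1) direct heterochromatin to the centromere repeats. The arms were 2.35-fold higher than wild type in dcr1Δ (log2 1.23, 0.84 to 1.5) and 1.81-fold higher in ago1Δ (0.85, 0.59 to 1.14), both at percentile 100.0 of random runs. The cenH-like stretch stood at 1.19 and 0.90, the edge of centromere 1 at 0.43 and 0.36 and that of centromere 3 at 0.75 and 0.74. The rest of the mating-type region stood at -0.13 in dcr1Δ and -0.37 in ago1Δ, and the subtelomere at -0.05 and -0.33. In ago1Δ, fba1, which encodes the glycolytic enzyme aldolase, was at 1.08 and cox7, which encodes a subunit of cytochrome c oxidase, at -1.21. The snoRNA gene SPNCRNA.1709 (1.13) was the single gene at least 1 higher in dcr1Δ, and a pair of tRNA genes, SPBTRNALEU.07 (-1.01) and SPCTRNALYS.10 (-1.10), were at least 1 lower. Directly compared, dcr1Δ exceeded ago1Δ by 0.31 over the arms, 0.24 over the mating-type region and 0.27 over the subtelomere. Over unique arm probes the differences from wild type were 0.37 and 0.08 (1.73 and 1.54 at the left end, 0.09 and -0.15 at the right), and after loess the centromere 2 centre turned from -0.27 to 0.35 in dcr1Δ and from -0.39 to 0.30 in ago1Δ, and the whole mating-type region in ago1Δ from -0.19 to 0.05.

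The swi6Δ, chp2Δ and double-mutant arrays ask what each of the heterochromatin protein 1 family members Swi6 and Chp2, which bind methylated H3 lysine 9, contributes. Over the arms the difference from wild type was 0.38 in swi6Δ (0.09 to 0.58), 0.72 in chp2Δ (0.45 to 0.94) and 1.21 in swi6Δ chp2Δ (0.99 to 1.44), which are 1.3-fold, 1.65-fold and 2.32-fold. Compared directly, the double mutant exceeded swi6Δ by 0.84 and chp2Δ by 0.51 over the arms, and by 0.21 and 0.24 over the mating-type region, where the first value was 0.09 without the cenH-like stretch and 0.08 after loess. Outside the cenH-like stretch, the mating-type region stood at 0.28, 0.10 and 0.39, and the subtelomere at 0.33, 0.27 and 0.12, so that the subtelomere in the double mutant lay -0.20 from swi6Δ and -0.17 from chp2Δ. At the subtelomere, the pseudogene SPAC212.07C stood at 0.81, 0.73 and 0.57, and tlh1 at 0.47 in chp2Δ and 0.42 in the double mutant. In chp2Δ the centre of centromere 2 was 1.00 above wild type, and the rRNA genes SPRRNA.42, SPRRNA.43, SPRRNA.44 and SPRRNA.47 stood at 1.14, 1.09, 1.08 and 1.08. Of the 2302 probes of the rDNA-like end of chromosome III 0 were unique, so rRNA genes there are not separate measurements, although they are counted singly below. Of the genes at least 1 from wild type, 0 were higher and 3 lower in swi6Δ, all tRNA genes, 8 were higher and 0 lower in chp2Δ, and 1 was higher and 2 lower in the double mutant, SPNCRNA.363 at 1.62, cox7 at -1.05 and SPBC18H10.05 at -1.11. Outlier marks left 1636 arm probes usable in chp2Δ, and over unique probes the arm differences were -0.01, -0.02 and 0.33, made up of 0.63, 1.03 and 1.82 at the left end and -0.21, -0.30 and 0.18 at the right. Keeping the marked spots put the chp2Δ subtelomere at 0.16, and loess put that of swi6Δ at 0.21. That of the double mutant ranged over the alternatives from 0.00 with quantile normalization to 0.27 with centring on euchromatic probes, and its difference from chp2Δ from -0.08 with background-subtracted signals to -0.28 with quantile normalization. The latter setting put its difference from swi6Δ at -0.36.

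The clr3Δ comparison concerns a histone deacetylase recruited to heterochromatin. H3-FLAG was 1.56-fold that of wild type over the arms (log2 0.64, 0.46 to 0.83, 94.7% of probes above 0) and stood 0.53 higher over the mating-type region (0.22 to 0.77), with 0.47 outside the cenH-like stretch and 0.61 within it. The edges of centromeres 1 and 3 stood at 0.34 and 0.53 and the subtelomere at 0.15. The gene at least 1 higher was SPNCRNA.352 (1.3), and the 3 genes at least 1 lower were the tRNA genes SPBTRNATYR.03 (-1.01), SPBTRNALEU.06 (-1.10) and SPCTRNALYS.10 (-1.36). The arms and the mating-type region lay above all random runs. Centring on euchromatic probes put the subtelomere at 0.39. With saturated spots left out it was at 0.05 and tlh1 went from 0.41 to -0.07, and over unique probes the arms stood at 0.30 (1.16 at the left end, 0.12 at the right).

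**Figure D2:**
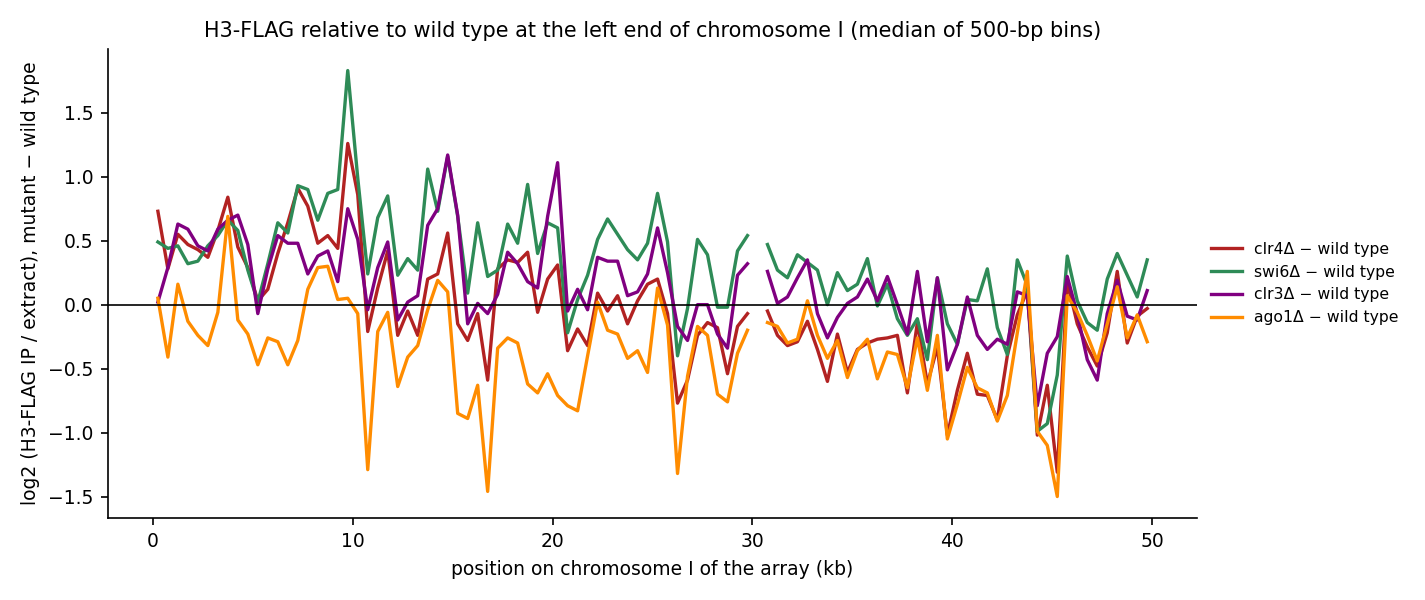
Difference in log2 H3-FLAG ratio from wild type (median of 500-bp bins) against position on the first 50 kb of chromosome I, for clr4Δ, swi6Δ, clr3Δ and ago1Δ. Over the terminal 30 kb the medians were 0.50 in swi6Δ, 0.30 in clr3Δ, 0.19 in clr4Δ and -0.30 in ago1Δ.

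The epe1 arrays ask how exchange depends on Epe1, a JmjC-domain protein that opposes heterochromatin. In epe1Δ the arms stood 0.42 above wild type (0.22 to 0.66, 1974 probes), the mating-type region at 0.01, the subtelomere at -0.20 and the centre of centromere 2 at 1.56. With epe1 overexpressed, the arms were 1.91-fold wild type (log2 0.94, 0.72 to 1.26, 97.3% of probes above 0), the mating-type region stood at 0.54, the subtelomere at 0.15 and the centre at 0.96. Directly compared, overexpression exceeded epe1Δ by 0.49 over the arms, 0.50 over the mating-type region and 0.33 over the subtelomere, the last from 0.20 with quantile normalization to 0.54 with centring on euchromatic probes. The noncoding RNA gene SPNCRNA.369 in the centromere 2 centre stood at 2.01 and SPNCRNA.352 at 1.62 under overexpression, while dpm2 (-1.18) was the lowest of 4 genes lower by 1 or more. In epe1Δ, SPNCRNA.1709 (1.27) and SPNCRNA.352 (1.09) were the 2 genes at least 1 higher, and ftm2 (-0.93) and SPAC212.12 (-0.72) stood lowest in the subtelomere. Over unique probes the arm difference was -0.56 in epe1Δ (0.24 at the left end, 28 probes, and -0.79 at the right, 45 probes), 0.34 under overexpression (1.86 and 0.13) and 1.34 between them, and centring on euchromatic probes put the subtelomere under overexpression at 0.38 while loess put it at 0.08. That of epe1Δ stood at -0.06 with quantile normalization and -0.12 with a common spread.

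The ago1Δ epe1Δ array asks whether the high centromeric exchange of ago1Δ needs Epe1, and lies on the same slide as ago1Δ and wild type. Relative to ago1Δ, the double mutant was 0.64-fold over the arms (log2 -0.65, -0.97 to -0.15, 3104 probes), and 20.7% of probes lay above 0. The cenH-like stretch stood at -0.92 (-1.1 to -0.59) and the edges of centromeres 1 and 3 at -0.61 and -0.69. Relative to wild type, these values were 0.23 for the arms, 0.03 for the cenH-like stretch, 0.03 for the centromere 1 edge and -0.03 for the centromere 3 edge, while the subtelomere stood at -0.27, or -0.15 with a common spread. The centre of centromere 2 went the other way, 1.43 above ago1Δ and 0.92 above wild type, with SPNCRNA.369 at 1.39 and 1.28. In the subtelomere tlh1 stood at -0.62 and SPAC212.12 at -1.06 against wild type, and per1, at the edge of centromere 1, at -1.02. Against ago1Δ, 5 genes were at least 1 higher, among them cox7 (1.21), the tRNA genes SPBTRNATYR.02 (1.26) and SPBTRNATYR.03 (1.29) and SPBC21B10.15 (1.35), and 0 were lower. The arm difference from ago1Δ lay below all random runs, whose lowest value was -0.29, and loess within the array moved it to -0.30 and the centre to 0.34, or 0.60 against wild type. Over unique arm probes the difference was -0.60 from ago1Δ (-1.08 at the left end, -0.39 at the right) and -0.19 from wild type (0.47 and -0.40), and the centre level of 1.04 lay below all 10000 lists matched on brightness (1.15 to 1.37).

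**Figure D3:**
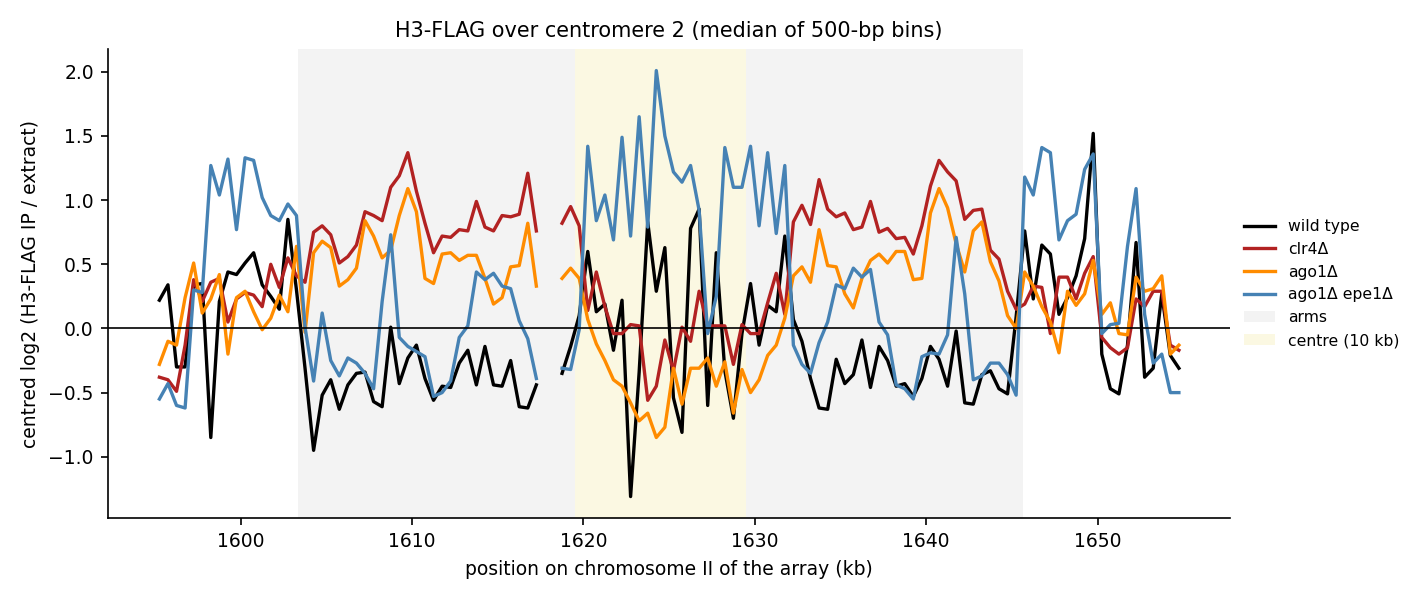
Centred log2 H3-FLAG ratio (median of 500-bp bins) against position on chromosome II in kb, for wild type, clr4Δ, ago1Δ and ago1Δ epe1Δ, with arms and centre shaded. Medians over the arms were 0.80 in clr4Δ, 0.48 in ago1Δ, -0.11 in ago1Δ epe1Δ and -0.36 in wild type, although the lines cross in places. In the shaded arm, ago1Δ epe1Δ runs above the others from 1629501 to 1632000. Most of that stretch lies within the domain between the inner tRNA genes (1621057 to 1630958). The right arm bounded by those genes starts at 1631923. Over the centre the ago1Δ epe1Δ median was the highest of the 4 (1.04), although in a few bins another line lies higher.

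The OFF and ON strains carry ura4 in place of the K region and differ in the epigenetic state of the mating-type locus, silenced or expressed. Both arrays lay on 1 slide. In the extract, the stretch from 25291 to 28660 of the mating-type contig was lost from both arrays (log2 -5.62 and -5.39 against the arrays of the first design). A deletion would give such a loss, but the stretch was delimited by the loss itself, without an independent position of the K region. In the cenH-like stretch next to the lost one, positions 31151 to 31460 were lost as well (-7.07 and -6.94, 26 probes). Away from those positions, 391 probes of the cenH-like stretch were 100.0% well above background in both extracts, possibly from centromere repeat DNA. That stretch is left out of the values for the silent region. Over the remaining silent region, ON exceeded OFF 1.35-fold (log2 0.44, 0.30 to 0.65, 1233 probes, 94.5% above 0), with 0.40 left and 0.48 right of the deleted part. The levels were 0.03 in ON and -0.50 in OFF. The ura4 gene, which encodes orotidine phosphate decarboxylase, stood 0.39 higher in ON (98 probes) and the tiled block around it 0.43 (0.34 to 0.51), though the place of this block on the reference is less sure than that of the others, whereas the block of mei4, a meiotic transcription factor gene, stood at -0.11. The ura4 probes cannot tell the inserted copy from any copy elsewhere. In the extract, the ura4 gene stood at 0.11 in OFF and 0.64 in ON relative to the array median. Relative to OFF, ON stood at -0.36 over the centromere 2 arms (-0.51 to -0.13), -0.23 over the subtelomere, with tlh1 at -0.55, and 0.32 over the centre of centromere 2, and the contig outside the inverted repeats (1 to 19230) stood at -0.04. Of 156 genes, 0 differed by 1 or more. The mating-type region lay above all random runs. The arms stood at -0.03 over unique probes (-0.17 at the left end, 0.03 at the right), and the centre of centromere 2 at 0.08 after loess.

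**Figure D4:**
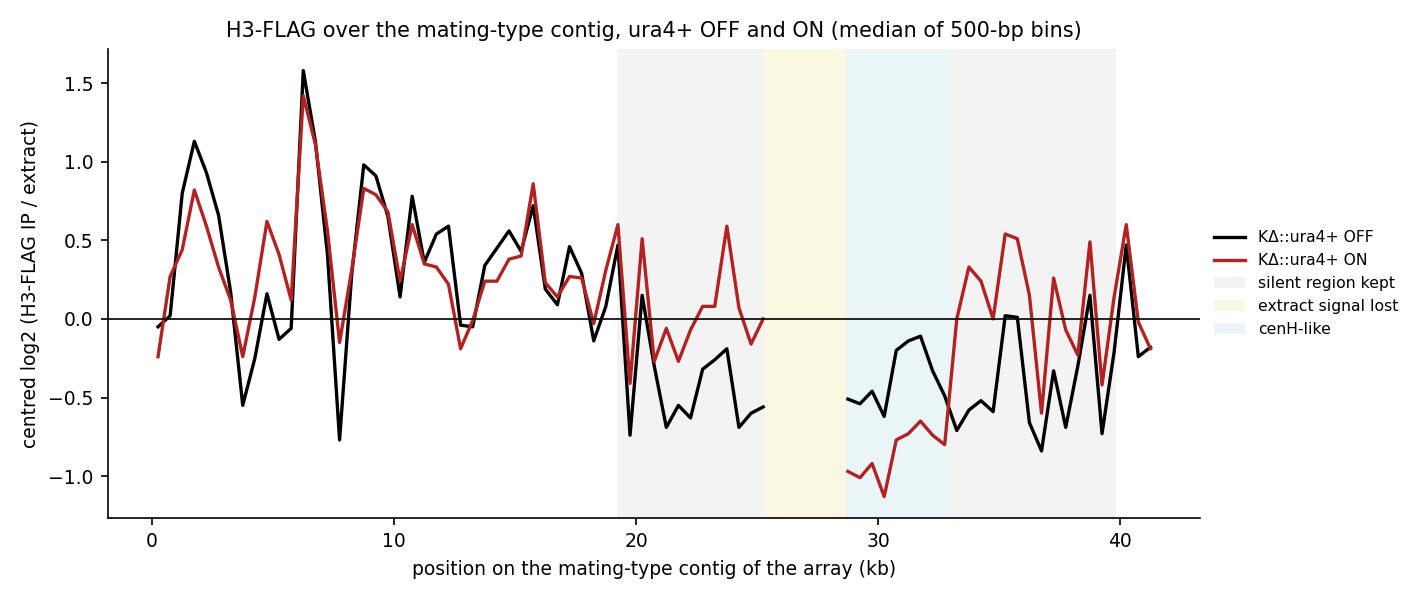
Centred log2 H3-FLAG ratio (median of 500-bp bins) of the OFF and ON strains against position on the mating-type contig in kb, with the kept silent region, the stretch lost from the extract and the cenH-like stretch shaded. ON runs above OFF over the kept silent region (median difference 0.44), and below it over the cenH-like stretch (-0.48).

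Summed over the comparisons with wild type, ago1Δ epe1Δ against ago1Δ and ON against OFF, 25 gene differences were at least 1 higher and 17 at least 1 lower. With centring on euchromatic probes these counts were 33 and 5, and with loess 32 and 9. Each of these comparisons measured 155 to 162 genes. In the simulations for clr4Δ against wild type, 1.0% of unchanged genes passed the same limit, and in those data 1 of 162 genes did. Where a comparison has only a few such genes, they cannot be told apart from calls without a change. The single genes named above carry that limit. Few members of the fixed gene lists were tiled. Of the ribosomal protein genes, 5 were measured (rpl1701, rpl26, rpl802, rpp202 and rps402), and in each of the 16 comparisons 0 were higher and 0 lower by 1 or more. Their median was 0.51 in ago1Δ against wild type (percentile 100.0 of random lists), 0.26 in chp2Δ (99.2), 0.23 in swi6Δ chp2Δ (99.4), 0.20 in clr4Δ (99.0) and -0.70 in ago1Δ epe1Δ against ago1Δ (0.0). Against wild type it was also 0.21 in epe1Δ (92.9), 0.11 in swi6Δ (90.2), 0.10 in dcr1Δ (96.9), 0.02 in clr3Δ (93.2), 0.02 under epe1 overexpression (89.4) and -0.20 in ago1Δ epe1Δ (35.4), and it was 0.01 in ON against OFF (89.1). The random gene lists were not matched on extract brightness. The ratio rose with brightness in ago1Δ (slope 0.062) and fell in wild type (-0.12) and ago1Δ epe1Δ (-0.2), so these percentiles do not separate brightness from genotype. Other fixed gene lists had a single tiled member each. Among these, pht1, the gene of the histone variant H2A.Z, lay below wild type in all 10 comparisons, from -0.31 in chp2Δ to -0.76 in ago1Δ epe1Δ, and kept that sign under each scaling and centring tried. All 10 share the same wild-type array, so the common sign can come from that array alone. Between mutants compared directly, pht1 differed by -0.27 (ago1Δ epe1Δ against ago1Δ) to 0.15 (swi6Δ chp2Δ against swi6Δ). In the 10 comparisons with wild type, the stress transcription factor gene atf1 lay between -0.22 and 0.14, yox1 of the MBF targets between -0.19 and 0.38, and tas3 of the heterochromatin factors between -0.16 and 0.31. Also against wild type, the glycolysis gene fba1 ranged from -0.62 in clr3Δ to 1.08 in ago1Δ and the helicase gene tlh1 from -0.62 in ago1Δ epe1Δ to 0.47 in chp2Δ. Both meiotic lists held mei4 alone, at -0.07 in ON against OFF, and the lists of manipulated and marker loci held ura4 alone. Lists of Tf2 elements, wtf genes, sucrose-responsive genes and mating genes had 0 tiled members.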

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

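The tests of brightness and of outlier marks for the opposite epe1Δ effects, the slide test and the brightness test on 3 arrays were chosen after the results were seen. The other tests here were written down before their results.

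Deleting epe1 shifted the centromere 2 arms in opposite directions with ago1 present and absent, and with 1 array per genotype the difference between backgrounds was not tested. With ago1 present the arms stood 0.42 above the strain with epe1, and without ago1 they stood at -0.65. The same arrays read the other way give 0.85 for ago1 deletion with epe1 present and -0.19 without epe1. At the left subtelomere of chromosome I, deleting epe1 gave -0.20 with ago1 and 0.09 without, deleting swi6 gave 0.33 with chp2 and -0.17 without, and deleting chp2 gave 0.27 with swi6 and -0.20 without. The 0.09 became 0.01 after loess, 0.00 with the terminal 30 kb, 0.21 with quantile normalization and 0.34 with a common spread. These differences were not tested either.

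A ratio that depends on brightness does not account for the whole of the opposite epe1 effects, because after loess they stood at 0.36 and -0.30, still 0.66 apart (1.07 before). Keeping outlier-marked spots left them 1.02 apart. A slide effect cannot be told apart from the genotype for the epe1Δ array, since 0 other arrays shared its slide. Over unique arm probes, which lie at the outer ends of the arms, the effects were -0.56 and -0.60, with opposite signs at the left end (0.24 and -1.08) and 1 sign at the right (-0.79 and -0.39). A dependence of Epe1 action on RNA interference was not tested.

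The level over the centromere 2 centre was 1.61 in epe1Δ, 1.25 in chp2Δ, 1.14 under epe1 overexpression and 1.04 in ago1Δ epe1Δ, and at most 0.23 on the other arrays of that design, a gap of 0.81. Subtracting euchromatic probes of equal GC content (median 28.3% in the centre, 36.7% in euchromatin) left a gap of 0.45, and keeping outlier-marked spots left 0.81, so neither accounts for the whole gap. After loess the gap shrank to 0.09 because ago1Δ epe1Δ fell to 0.24, which leaves brightness open for that array, whose level also lay below all lists of euchromatic probes of like brightness (1.15 to 1.37), while chp2Δ, epe1Δ and epe1 overexpression kept a gap of 0.61. Of these arrays, chp2Δ, epe1Δ and epe1 overexpression each had a slide of their own, so slide and genotype could account for their levels alike. Deletion and overexpression of epe1 both show a high centre, and no biological explanation was tested.

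The cenH-like stretch of the mating-type region went with the centromere arms, at 1.11 in clr4Δ against wild type where the rest of the region stood at -0.02. Its probes could hybridise with DNA of the centromere repeats, and the K-deletion strains bear on this. There the stretch stood at -0.48 in ON against OFF (-0.55 to -0.41, 404 usable probes), near the arms (-0.36) and far from the rest of the region (0.44), while its extract signal stayed well above background on 100.0% of 391 probes. That count leaves out probes in and next to positions 31151 to 31460, which both extracts lost (-7.07 and -6.94, 26 probes), while some of the 404 lie there. A deletion that spans the stretch, with the other probes reading repeat DNA from elsewhere, would give this pattern. The limits of the stretch are not independent of these arrays, since it starts where their extract loss ends. Its end at 33000 is a fixed limit at which the ON level steps from -0.8 to -0.0 between 500-bp bins. The closeness to the arms is thus not an independent check. After loess the stretch still stood 0.45 above the rest in clr4Δ (0.65 against 0.20), which argues against brightness as the whole cause. A true change at cenH itself, where RNA interference also acts, stays open for the strains that carry the K region.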

How the results depend on the processing

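Keeping outlier-marked spots, leaving out saturated spots, bounding the centromere by the inner tRNA genes and leaving out the cenH-like stretch were chosen after the data were seen. The yardstick was too: an alternative counts as moved when it lies over 1 SD over probes from the reported value, a choice made after a narrower one, the spread over random runs, had been tried. Of 1368 alternatives to 116 region values, 1340 stayed within that SD, 12 moved and 16 reversed, where a reversal was a change of sign in a value larger than the spread over random runs. Counting smaller values, 54 changed sign, among them with loess the wild-type centre (0.11 to -0.35), the swi6Δ chp2Δ centre (0.04 to -0.21) and the ago1Δ epe1Δ arms (-0.11 to 0.03), and with normexp the swi6Δ centre against wild type (0.06 to -0.40). With the narrower spread 291 moved and 16 reversed. Whatever the spread, 269 changed by over 1.5 times or in sign. Background-subtracted signals, both channels above background, no dim-probe filter, means, quantile normalization and a common spread moved or reversed 0 region values by the wider yardstick, which sets a median over many probes against the SD of single probes and so says little, and moved 5, 0, 3, 22, 32 and 37 of 116 by the narrower. The cause of the changes below was not tested, except that unique probes are 3.9% of arm probes and 7.5% of subtelomere probes.

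With unique probes, arm levels were -0.14 in wild type, 0.26 in clr4Δ, -0.12 in chp2Δ, 0.26 in swi6Δ chp2Δ and -0.80 in epe1Δ. Arm differences from wild type were 0.22 in clr4Δ, 0.37 in dcr1Δ, -0.01 in swi6Δ, -0.02 in chp2Δ, 0.33 in swi6Δ chp2Δ, -0.56 in epe1Δ, 0.08 in ago1Δ, -0.19 in ago1Δ epe1Δ and 0.34 under epe1 overexpression. Overexpression against epe1Δ gave 1.34 and ON against OFF -0.03, and the dcr1Δ subtelomere turned from -0.05 to 0.02. With loess, the centre stood at 0.24 in ago1Δ epe1Δ, at 0.35 (dcr1Δ) and 0.30 (ago1Δ) against wild type and at 0.34 in ago1Δ epe1Δ against ago1Δ. The mating-type region turned to 0.05 in ago1Δ and to -0.18 in ago1Δ epe1Δ against ago1Δ, and SPCP20C8.03 to 0.21 in the latter comparison. With normexp the swi6Δ centre level turned to -0.28 and SPNCRNA.369 in swi6Δ to -0.35. Centring on euchromatic probes, whose medians after centring on all probes ran from -0.21 (clr3Δ) to 0.14 (OFF), turned subtelomere levels to 0.05 in clr3Δ and 0.07 under overexpression and the clr4Δ difference to 0.03. The 30-kb subtelomere turned that difference to 0.19. Without the cenH-like stretch the clr4Δ mating-type difference turned to -0.02. Without saturated spots tlh1 in clr3Δ turned to -0.07, and with quantile normalization SPBTRNAVAL.07 in clr3Δ turned to 0.01. Against random runs in place of matched lists, percentiles for the centre turned to 100.0 (ago1Δ epe1Δ level), 1.5 (dcr1Δ difference) and 0.0 (ago1Δ difference).

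Of 1655 alternatives to named gene values, 127 moved and 4 reversed, and 33 of 116 percentiles moved. Gene differences of at least 1, 42 in all, numbered 27 with a common spread, 28 with quantile normalization, 37 with normexp, 38 with centring on euchromatic probes, 40 with outlier-marked spots kept, 41 with loess, 41 with no dim-probe filter, 42 with both channels above background, 43 with background-subtracted signals, 51 with medians in place of means and 22 with unique probes, which left fewer genes to measure (125 in place of 162 in clr4Δ). The 100-kb subtelomere was not run because 50 kb was tiled, and unique probes gave no value for the mating-type region. No paired analysis was possible because each genotype had 1 array. At least 97.0% of extract signals per array were well above background, but of 994 probes in the centromere 2 centre 676 were usable under epe1 overexpression, 581 in epe1Δ and 554 in chp2Δ. With no filter on dim probes these levels went from 1.14 to 1.20, from 1.61 to 1.28 and from 1.25 to 1.13.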

Other observations

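No tests of explanations are reported in this part, and the features named were chosen after their values were seen.

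Within euchromatin, promoters and other intergenic probes (outside protein-coding genes) had higher H3-FLAG ratios than gene bodies in wild type. Over 117 genes, probes within 250 bp upstream of genes had a median of 0.76 (0.15 to 1.31, 2317 probes), other intergenic probes 0.52 and gene bodies -0.10. In the same order the medians were 1.01, 0.72 and -0.27 in ago1Δ epe1Δ, 0.14, 0.23 and -0.17 in clr4Δ and 0.25, 0.35 and -0.08 in dcr1Δ. Intergenic probes also exceeded promoters in swi6Δ, clr3Δ, epe1Δ and epe1 overexpression, so the contrast with gene bodies was not particular to promoters. On the arrays of the K-deletion strains the medians were 0.22, 0.18 and 0.09 in ON and 0.02, 0.02 and 0.17 in OFF. Promoter probes were dim in the extract, at -3.42 on the log2 scale relative to the array median in wild type, against 0.53 for gene bodies. The ratio fell with extract brightness in wild type (slope -0.12, r -0.388) and ago1Δ epe1Δ (-0.2), and rose in OFF (0.075). It also rose in clr4Δ (0.015), dcr1Δ (0.05) and ago1Δ (0.062), where promoters still exceeded gene bodies. No loess or brightness-matched values were made for these classes, so the part that brightness plays was not tested.

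Near the left end of chromosome III, the stretch from 23131 to 50000 differed in sign from the subtelomere of chromosome I in swi6Δ (-0.23 against 0.33), chp2Δ (-0.15 against 0.27), swi6Δ chp2Δ (-0.31 against 0.12) and epe1 overexpression (-0.36 against 0.15), each relative to wild type. Both had 1 sign in clr4Δ (-0.30 and -0.10), dcr1Δ (-0.32 and -0.05), ago1Δ (-0.30 and -0.33), epe1Δ (-0.03 and -0.20), ago1Δ epe1Δ (-0.11 and -0.27) and clr3Δ (0.04 and 0.15), although the subtelomere turned to 0.03 in clr4Δ with centring on euchromatic probes and to 0.02 in dcr1Δ with unique probes, and in swi6Δ chp2Δ it stood at 0.00 with quantile normalization. SPCC1884.01, a gene in that stretch, stood at -0.43 in clr4Δ, -0.45 in dcr1Δ and -0.64 under epe1 overexpression. The rDNA-like end, where 0 of 2302 probes were unique, stood at 1.07 in chp2Δ, 0.30 in swi6Δ chp2Δ and 0.21 in epe1Δ, and between -0.15 and 0.14 in the other 7 genotypes. Alternatives were not run for these 2 stretches of chromosome III.

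In the extract itself, the clr3Δ array was 1.36 brighter than the other arrays of its design over the mating-type stretch lost in the K-deletion strains (25291 to 28660), and the epe1 overexpression array was 1.56 brighter over 31151 to 31460.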
